A study of Macaca mulatta with 5 samples.

How the data were processed

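The series followed rhesus macaque embryonic stem cells of line 366.4 through a staged culture towards serotonin neurons, on Affymetrix rhesus expression arrays. Per the labels, 1 array was hybridised for each of 5 stages, so the series holds 5 arrays and no replicates. The stages were undifferentiated cells on a layer of mouse embryonic fibroblasts (ESC, passage 13), embryoid bodies after 6 to 8 days (EB), neurospheres after 7 to 9 days of selection in a medium with N2 supplement (N1), cells expanded with FGF4 for 7 to 9 days (N2), and cells matured without FGF4 on a reduced growth factor matrix (N3). RNA was extracted with a Qiagen kit and labelled with biotin, per the labels' protocols.

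The values deposited by the authors are array intensities on a linear scale, 1 per probe set and array. The submitters' processing notes name GCOS 1.0, Affymetrix's array software. The algorithm, the scaling target and the detection calls are not given in the sources used here. Over the non-control probe sets, the mean of the deposited intensities with 2% trimmed from each end was between 199.1 and 199.3 on the 5 arrays, so the values had already been scaled to a common level. No scanner files were used here.

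Each array was rescaled to a 2% trimmed mean of 500, which multiplied the values by 2.508 to 2.511. Values below 100 were then set to a floor of 100 and the log2 was taken. All signals in the text are on this scale before the floor was applied. All 42 negative control probe sets stayed below 100 on every array. A further 674 probe sets have names starting with NC- and were not counted among the controls. Of these, 61 reached 100 or more in ESC, 10 in EB, 22 in N1, 16 in N2 and 19 in N3, and 3 reached 200 in ESC. What they measure was not established. A ratio with 1 side at the floor is a bound and is written as "at least". No ratio is given where both sides were at the floor.

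Probe sets were named from the GEO platform annotation, which can be old. Of 52865 probe sets, 158 were controls. The annotation table listed 25330 probe sets, of which 24969 had 1 gene symbol and 361 had several, while 27535 were not listed and stay unnamed. Entrez identifiers of 24629 listed probe sets matched a RefSeq gene table, and no symbol needed updating. No coordinates are given, because no genome build was named for the array. A gene was represented by the probe set with the highest mean log2 signal among those with exactly 1 symbol, which gave 14132 genes. A gene counted as measured in a comparison when it lay above the floor on at least 1 of the 2 arrays.

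The comparisons were each stage against the stage before it and N3 against ESC. With 1 array on each side there is no test, standard error or p-value, and no difference has a replicate check. The number of arrays limits the precision. Genes were counted when the later stage was at least 2-fold higher or lower. The only technical spread that could be had was the disagreement between the 2 brightest probe sets of the same gene. It is given as the SD of the difference between their log2 ratios, divided by the square root of 2. It is not a replicate spread.

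Before the data were examined, 31 gene lists were written for the expected lineages, for other cell types the cultures could hold and for pathways. They name 469 genes, of which 315 have a probe set here and 154 do not. For each list and comparison the median log2 ratio of the measured members was set among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart at or below percentile 2.5 or at or above percentile 97.5. The percentile describes these arrays and is not a p-value. Of 155 pairs of list and comparison, 68 stood apart, 44 above and 24 below, where 7.8 would do so if the lists were random. In 24 pairs the median and the mean of the list differed in sign.

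Genes named in the text follow a rule also fixed before the data were examined. It takes the 5 genes with the largest difference each way in each adjacent comparison and the 10 each way for N3 against ESC, among named genes at 100 or more on both arrays and 200 or more on the brighter. It further takes the 5 genes per stage with the largest ratio to the next highest stage, among genes above the floor in that next stage and at 200 or more in their own, up to 6 members of a list per comparison at 2-fold or more, and 19 markers given whatever their value. Of those 19, 14 have a probe set here. NES, MAP2, SLC6A4, DDC and MAOB were not analysed here. Where any other gene is named, the text says that it was chosen after its values were seen.

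The alternatives were 4 other scalings between arrays (values as deposited, quantile normalisation, equal medians, and the 27 hybridisation control probe sets), floors of 50 and 200, no floor with log2(value + 1), the median of a gene's probe sets, leaving out probe sets marked as able to bind related transcripts, a 4-fold threshold and unmatched random lists. Comparisons that skip the ESC, EB or N2 array were added after the data were examined. The counting and the list percentiles were tested on simulated data with the probe set spread of each comparison as noise. Changes were planted only in bright genes, well clear of the floor, so recovery among dimmer genes was not measured. Of such bright genes, changes of 1.5 on the log2 scale were recovered for 70.0% in EB against ESC, 95.0% in N1 against EB, 83.0% in N2 against N1, 93.0% in N3 against N2 and 77.0% in N3 against ESC. Of 13932 unchanged genes, that noise took 1312 past 2-fold in EB against ESC, 164 in N1 against EB, 486 in N2 against N1, 128 in N3 against N2 and 1553 in N3 against ESC. Simulated lists of 12 bright genes raised by 1 on the log2 scale stood apart above for 38 to 40 of 40 lists per comparison. Without a shift, 0 to 4 of 40 lists stood apart. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.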

Results

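Messenger RNA was profiled at 5 stages of a rhesus macaque embryonic stem cell culture directed towards serotonin neurons, the brainstem neurons that make and release serotonin. Each stage (ESC, EB, N1, N2 and N3) was represented by 1 array, so every value below is a single measurement and no difference could be set against a replicate spread. Of 14132 named genes, 10325 lay at or above the floor of 100 in ESC, 9551 in EB, 10047 in N1, 9888 in N2 and 9950 in N3. Across 34859 probe sets the Pearson correlation of log2 signal was 0.962 between EB and N1 and also between N2 and N3, whereas ESC correlated with the later stages at 0.793 to 0.865. These correlations run across probe sets of the same arrays, which are not independent replicates.

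The arrays differed in RNA quality and background. The signal of the 3' actin control probe set exceeded that of the 5' one by 1.73-fold in ESC, 15.19-fold in EB, 5.43-fold in N1, 25.21-fold in N2 and 8.63-fold in N3. For GAPDH the same ratio was 1.94 in ESC, 2.78 in EB, 1.69 in N1, 7.1 in N2 and 2.1 in N3. For the EF1a control transcript it was 0.86 in ESC, 0.96 in EB, 0.83 in N1, 1.88 in N2 and 1.06 in N3. The highest negative control reached 87.2 in ESC and between 47.6 and 64.8 on the other arrays. Among the 5 comparisons, the SD between probe sets of a gene was largest for those with ESC, at 0.739 for N3 against ESC and 0.684 for EB against ESC on the log2 scale, and was 0.524 for N2 against N1, 0.42 for N1 against EB and 0.414 for N3 against N2.

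**Figure D1:**
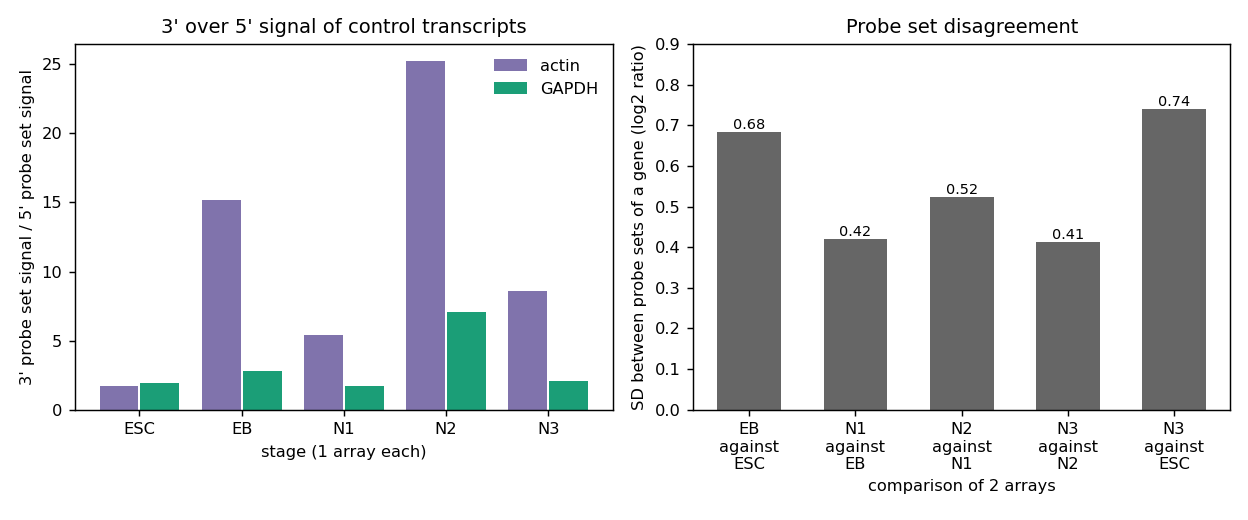
Left, ratio of 3' to 5' control probe set signal for actin and GAPDH, with 1 bar per array and transcript, and an actin ratio from 1.73 in ESC to 25.21 in N2. Right, SD of the difference between the log2 ratios of the 2 brightest probe sets of a gene, divided by the square root of 2. It runs from 0.414 in N3 against N2 to 0.739 in N3 against ESC.

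The comparison of EB with ESC asked what changed when stem cells left the feeder layer and aggregated. Genes of undifferentiated cells were lower. The lists of mesoderm and heart, endoderm, trophoblast, and endothelial and blood genes had medians above those of random lists. POU5F1, a core pluripotency factor, was 31.6-fold lower (28621 in ESC and 906 in EB). DPPA4 was at least 46.8-fold lower and the DNA methyltransferase gene DNMT3B 8.38-fold lower. Of 11 measured pluripotency genes, 7 were at least 2-fold lower and 0 higher, and the list median of -1.06 lay at percentile 0.0 of random lists. NANOG, also a pluripotency factor, differed by 1.12-fold (1047 and 1178) on its single probe set.

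Heart and mesoderm genes were higher in EB for 8 of 13 measured members and lower for 1, with a median log2 ratio of 2.12 (percentile 100). The heart muscle genes MYL7 and TNNT2 were 29.4-fold and 28.5-fold higher, MYH6 was at least 25.0-fold higher (other measured probe sets at log2 ratios of 2.73 and -0.20), and the transcription factor HAND1 was 34.2-fold higher. Of 11 endoderm genes 6 were higher and 1 lower (median 1.60, percentile 100), but the median was 0.60 at percentile 96.7 without probe sets marked as able to bind related transcripts. They included the fibrinogen gene FGB (at least 263-fold), the apolipoprotein gene APOA1 (27.4-fold) and the transcription factor GATA6 (23.9-fold), while CER1 was at least 3.98-fold lower. The endothelial and blood list had 6 measured genes, and 6 were at least 2-fold higher (median 2.36, percentile 100), among them PECAM1 (10.3-fold) and CDH5 (at least 9.19-fold), although the other measured probe set of TEK moved the opposite way by over 2-fold and that of CDH5 had a log2 ratio of 0.13. In the trophoblast list 4 of 6 members were higher, CDX2 by at least 31.4-fold and GATA3 by 11.3-fold, and 2 were lower, TFAP2C by 3.56-fold and KRT7 by at least 3.52-fold (median 2.56, percentile 100, and 93.2 with no floor). Its members GCM1, ELF5 and CYP19A1, named after their values were seen, were below the floor on both arrays. The listed genes CGA, CGB3 and ERVW-1 have no probe set here.

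HOX genes of the hindbrain and neck groups were higher for 5 of 7 measured members and lower for 0 (median 2.47, percentile 100), with HOXA3 at least 17.5-fold and HOXA5 6.59-fold higher. The WNT response list had a median of 1.11 (percentile 100), with AXIN2, a WNT target, 4.12-fold and DKK1 8.5-fold higher, and SFRP1 6.62-fold lower. That median was -0.21 at percentile 36.2 when a gene was the median of its probe sets, and the list lay at percentile 96.9 with no floor. The other measured probe set of AXIN2 had a log2 ratio of 0.55. Matrix genes were split, with 4 of 12 members higher, such as LUM (at least 175-fold) and DCN (at least 71.9-fold), and 5 lower, such as TAGLN (7.69-fold) and THY1 (8.67-fold). Their median of -0.63 lay at percentile 0.2 while their mean was 0.72, and the list did not stand apart with the median of probe sets (-0.08, percentile 56.6) or without probe sets able to bind related transcripts (percentile 5.5). The ESC grew on a layer of mouse fibroblasts. How far mouse RNA added to the ESC signal of genes such as TAGLN, THY1, SPP1, ACTG2 and CAV1 was not measured. Synaptic genes had a median of -1.18 (percentile 2.1), with SYT1 12.7-fold lower, but the median was 0.06 with no floor and the list did not stand apart in 7 other settings, such as a floor of 50 (-0.07, percentile 70.6) and scaling to equal medians (-0.69, percentile 2.6). Serotonin neuron genes had a median of 0.83 (percentile 99.2, and 97.2 after quantile normalisation). Of 9 measured members, the 1 at least 2-fold higher was GATA3, which is also in the trophoblast list, and HTR1B was at least 2.44-fold lower. In the ventral hindbrain list (median 0.60, percentile 97.6) the transcription factor genes FOXA1 and FOXA2, which also act in endoderm, were at least 44.6-fold and at least 6.17-fold higher. GABA neuron genes had a median of 0.50 (percentile 98.6), with GAD1 at least 5.26-fold higher, and cholesterol synthesis genes 0.74 (percentile 98.3), with CYP51A1 4.31-fold higher and DHCR7 2.36-fold lower. Other measured probe sets of GAD1, GAD2 and CYP51A1 had log2 ratios of 0.67, 0.03 and 0.62. These 3 lists did not stand apart in some settings. Ventral hindbrain genes lay at percentile 97.0 after quantile normalisation, 97.2 with no floor and 94.2 without probe sets able to bind related transcripts, and cholesterol genes at 65.9 with the median of probe sets and 89.7 without those probe sets. GABA genes lay at 94.2 with no floor, 97.0 with the median of probe sets and 92.3 against unmatched random lists.

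Among genes above the floor on both arrays, the largest differences were the imprinted transcript H19 (126-fold higher), SPINK1 (120-fold), the imprinted gene DLK1 (65.5-fold), TGFBI (46.5-fold) and the angiotensin receptor gene AGTR1 (45.6-fold). The largest lower ones were the secreted phosphoprotein gene SPP1 (71.1-fold lower), the smooth muscle actin gene ACTG2 (38.9-fold), CAV1 (33.3-fold), POU5F1 and GPC4 (24.7-fold). In total 1332 genes were at least 2-fold higher in EB and 1290 lower, of 10978 measured. The higher genes made up 50.8% of these, 37.6% (888 higher and 1472 lower) with the median of a gene's probe sets, 38.8% with no floor, and 80.1% when arrays were scaled to equal medians, which moved the median log2 ratio of all measured genes from -0.06 to 0.41. Scaling to hybridisation controls moved that median to 0.06. The actin 3' to 5' ratio was 15.19 in EB and 1.73 in ESC, and the GAPDH ratio 2.78 and 1.94. Among 654 genes past 2-fold with a second measured probe set, that probe set moved the same way for 80.6% and also passed 2-fold for 40.7%.

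**Figure D2:**
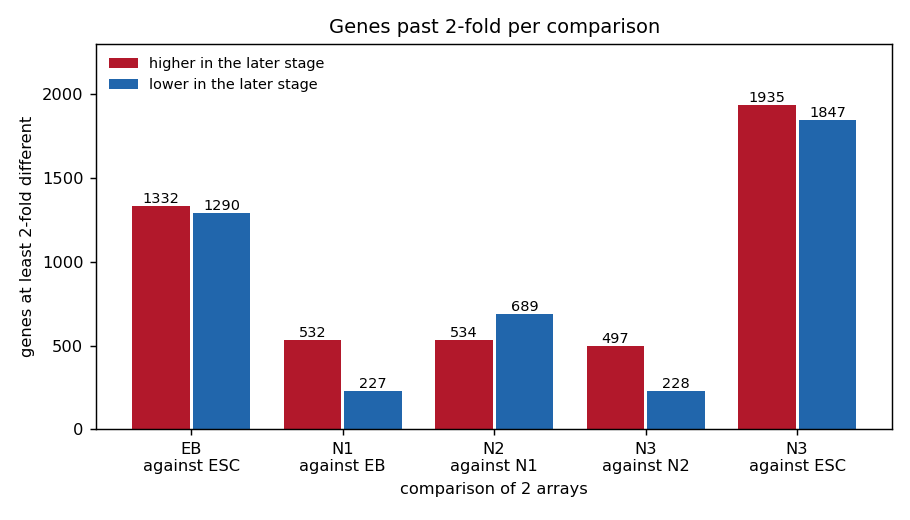
Number of genes at least 2-fold higher (red) or lower (blue) in the later stage of each comparison, with 1 array on each side. EB against ESC and N3 against ESC have the most genes past 2-fold, with 1332 higher and 1290 lower, and 1935 higher and 1847 lower.

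N1 against EB showed the first step of neural selection. Neuronal genes were higher for 10 of 16 measured members and lower for 0, with a median of 1.38 (percentile 100). The RNA-binding protein gene ELAVL2 was 8.2-fold higher, the tubulin regulator gene STMN2 6.34-fold (1986 in EB and 12594 in N1), TUBB3 4.3-fold and DCX, a microtubule gene of migrating neurons, 4.16-fold. TUBB3 was 3684 in ESC, 663 in EB and 2852 in N1. In EB against ESC the neuronal list had not stood apart (median -0.23, percentile 23.8), with 4 of 14 members higher and 4 lower. The synaptic list did not stand apart (median 0.48, percentile 94.5), and SYT4, at least 11.5-fold higher, was the 1 of 9 measured members past 2-fold. Early neural progenitor genes had a median of 0.37 (percentile 99.8), with HES6 2.87-fold and SOX11 2.47-fold higher, whereas PAX6 was 419 in EB and 306 in N1, and the list lay at percentile 74.7 with the median of a gene's probe sets.

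Genes of blood vessels, trophoblast and heart were lower relative to random lists, whereas endoderm genes did not stand apart (median -0.25, percentile 11.8), with 2 of 10 members higher and 1 lower. The endothelial and blood list had a median of -1.03 (percentile 0.0), with CDH5 2.95-fold lower (log2 ratio of -0.13 on its other measured probe set), and the trophoblast list -0.85 (percentile 0.0), with CDX2 2.56-fold lower. For CDX2, the other measured probe set had a log2 ratio of -0.38. The mesoderm and heart list stood at -0.44 (percentile 0.6), with TNNT2 2.23-fold lower. Proliferation genes had a median of -0.46 (percentile 0.4) with 0 of 14 members past 2-fold, WNT response genes -0.45 (percentile 0.7) and hypoxia and glycolysis genes -0.42 (percentile 1.8). Scaling to the hybridisation controls, which placed the median of all measured genes at 0.41, moved these 4 medians to 0.03, 0.01, 0.04 and 0.04, at percentiles 0.5, 0.4, 0.9 and 1.3, so they still stood apart below other genes. With the median of a gene's probe sets, the proliferation, WNT and hypoxia lists lay at percentiles 21.9, 18.1 and 16.4, and hypoxia genes lay at 2.7 after quantile normalisation. Without probe sets able to bind related transcripts, proliferation genes lay at percentile 5.5 and hypoxia genes narrowly inside the limit. Pluripotency genes had a median of -0.64 (percentile 0.0), with POU5F1 3.64-fold and SALL4 3.46-fold lower. Cholesterol synthesis genes stood at 0.37 (percentile 99.9, and narrowly inside the limit against unmatched random lists), with 0 of 8 members past 2-fold. The fibroblast and matrix median of 0.07 (percentile 98.7) was -0.29 with equal medians, still at percentile 98.5, since that scaling placed the median of all measured genes at -0.37. The ribosomal protein median of 0.02 (percentile 97.7) was -0.35 with equal medians, also at percentile 97.7, and -0.04 at percentile 59.6 after quantile normalisation. Against unmatched random lists these lay at percentiles 72.1 and 58.2, and ribosomal protein genes also did not stand apart with a floor of 50, a floor of 200 or no floor (percentiles 96.9, 89.6 and 97.4), with values as deposited (97.4) or with the median of probe sets (79.7).

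Among genes above the floor on both arrays, the largest differences were MAP6D1 (17.1-fold higher), the neuroendocrine transcription factor INSM1 (13.9-fold), EBF1 (10.6-fold), the plasma protein gene ITIH1 (10.3-fold) and the embryonic haemoglobin gene HBE1 (9.28-fold). The other measured probe set of EBF1 had a log2 ratio of 0.07. The gastrin and cholecystokinin receptor gene CCKBR was 6.32-fold lower, the lipid transfer gene MTTP 4.4-fold, the retinoic acid-degrading enzyme gene CYP26A1 4.23-fold, SHF 4.18-fold and CREB3L3 4.09-fold. For MTTP, the other measured probe set had a log2 ratio of -0.82. Of 10335 measured genes, 532 were higher and 227 lower. The higher share of 70.1% became 52.1% after quantile normalisation, 24.8% with equal medians and 95.2% with hybridisation controls. The median of all measured genes was -0.02 before these changes of scaling.

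N2 against N1 compared cells expanded with FGF4 with the neurospheres before them. Neural progenitor genes were higher for 6 of 10 measured members and lower for 0 (median 1.27, percentile 100). PAX6, a transcription factor of neural stem cells, was 10.8-fold higher (306 in N1 and 3301 in N2), the Notch target HES5 4.39-fold, the Notch ligand gene DLL1 3.1-fold and SOX2 2.64-fold. Other measured probe sets had log2 ratios of -0.42 for HES5, 0.49 for DLL1, and 0.30 and -0.18 for SOX2. Neuronal genes (median 1.00), synaptic genes (1.00), GABA neuron genes (1.31) and glutamate neuron genes (1.43) all lay at percentile 100. L1CAM was 4.74-fold higher, SYT4 4.78-fold, the GABA-synthesising enzyme gene GAD2 3.1-fold and the glutamate receptor gene GRIA4 3.4-fold, while TUBB3 was 2852 in N1 and 1819 in N2. L1CAM was 2239 in ESC, 451 in N1 and 2140 in N2.

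FGF response genes had a median of 0.40 (percentile 99.0), with the FGF feedback genes SPRY2 2.99-fold and SPRY4 2.44-fold higher. For SPRY2, a second measured probe set had a log2 ratio of 0.52. Notch pathway genes stood at 0.49 (percentile 99.7), hypoxia and glycolysis genes at 0.48 (percentile 99.9) and neural crest genes at 0.47 (percentile 98.5). Scaling to hybridisation controls, which placed the median of all measured genes at -0.57, moved these 4 medians to -0.15, -0.09, -0.10 and -0.11, at percentiles 97.8, 99.1, 99.4 and 98.8, so they still stood apart above other genes. With the median of a gene's probe sets, the FGF, hypoxia and neural crest lists lay at percentiles 69.2, 92.0 and 71.5, and neural crest genes lay at 97.4 after quantile normalisation. Without probe sets able to bind related transcripts, hypoxia genes lay at 82.0. The fibroblast and matrix list stood at 0.58 (percentile 100), with FBN1 3.06-fold and COL1A2 2.06-fold higher (other FBN1 probe sets at log2 ratios of -0.03, -0.26 and 0.72), and at percentile 96.7 without those probe sets. Endoderm genes were lower for 5 of 10 members and higher for 0 (median -0.97, percentile 0.0), including FGB (4.8-fold) and APOA1 (3.46-fold). Epithelial genes had a median of -0.86 (percentile 0.1), with the keratin gene KRT8 13.4-fold lower on its single probe set, while KRT18 was 1097 in N1 and 869 in N2. Mesoderm and heart genes had a median of -0.72 (percentile 0.1), endothelial and blood genes -0.75 (percentile 2.3) and proliferation genes -0.44 (percentile 0.2). The endothelial and blood list did not stand apart with a floor of 50 (percentile 4.5), no floor (-0.29, percentile 27.2) or the median of probe sets (-0.49, percentile 13.8). The other measured probe set of GAD2 had a log2 ratio of -0.50.

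The largest higher genes above the floor on both arrays were the embryonic skeletal myosin gene MYH3 (28.3-fold), FGFBP3 (16.4-fold), the skeletal myosin light chain gene MYL1 (15.8-fold), the activin subunit gene INHBA (12.9-fold) and the neuronal membrane gene GPM6A (11.1-fold). The other measured probe set of FGFBP3 had a log2 ratio of -0.19. With the same limit, the largest lower genes were HBE1 (17.6-fold), the haemoglobin gene HBG2 (16.5-fold), KRT8, the fibrinogen gene FGG (10.7-fold) and SERPIND1 (8.09-fold). Of 10552 measured genes, 534 were higher and 689 lower. The higher share of 43.7% became 54.8% with equal medians, 31.3% with the median of probe sets and 6.8% with hybridisation controls, and the median of all measured genes was -0.04 before that change. The N2 array had the highest actin 3' to 5' ratio of the series, 25.21, and N3 against N1, which skips it, had 897 genes higher and 710 lower.

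N3 against N2 followed the withdrawal of FGF4. Neuronal genes were again higher relative to random lists (median 0.60, percentile 100), with 3 of 17 members past 2-fold. TUBB3 was 4.17-fold higher (1819 in N2 and 7590 in N3), the axon guidance gene CRMP1 3.21-fold and STMN4 2.73-fold. Synaptic genes had a median of 0.49 (percentile 99.8), early neural progenitor genes 0.42 (percentile 100), Notch genes 0.39 (percentile 98.4) and hypoxia and glycolysis genes 0.30 (percentile 99.6, and 95.4 against unmatched random lists). Notch genes did not stand apart after quantile normalisation (percentile 94.5), with hybridisation controls (96.4) or with the median of probe sets (77.8). GAD1, which encodes a GABA-synthesising enzyme, was 4.84-fold higher, and the astrocyte glutamate transporter gene SLC1A2 3.58-fold, but neither the GABA neuron list (median 0.18, percentile 78.3) nor the astrocyte list (0.08, percentile 79.5) stood apart. HES5 was 2.15-fold higher and HES1 5.84-fold lower. After FGF4 was withdrawn, FGF response genes did not stand apart (median 0.21, percentile 90.4), with 0 of 12 members past 2-fold. SPRY2 was 5350 in N2 and 8842 in N3.

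Proliferation genes had a median of -0.55 (percentile 0.0), with 0 of 14 members past 2-fold. Endoderm genes stood at -0.52 (percentile 0.1, but -0.21 at percentile 14.4 without probe sets able to bind related transcripts), trophoblast genes at -0.93 (percentile 0.1), endothelial and blood genes at -0.97 (percentile 0.0) and epithelial genes at -0.51 (percentile 0.4). FGB was at least 32.2-fold lower, CDX2 2.96-fold, PECAM1 at least 3.0-fold and EPCAM 3.22-fold, while other measured probe sets of CDX2 and PECAM1 had log2 ratios of -0.08 and -0.01. The mesoderm and heart list had a median of 0.34 (percentile 97.9) and was split. It did not stand apart with a floor of 50, with no floor or without probe sets able to bind related transcripts (0.15 in each, percentiles 79.8, 81.2 and 83.9), nor against unmatched random lists (96.2). MYL4 was 4.69-fold and TNNT2 2.88-fold higher, and HAND1 was 4.63-fold and TBX5 2.38-fold lower. The rise of MYL4 followed a low value on the N2 array (1402 in N1, 248 in N2 and 1164 in N3). Fibroblast and matrix genes had a median of 0.19 (percentile 99.7), with 0 of 12 members past 2-fold, and lay at percentile 82.7 with the median of probe sets and 89.6 against unmatched random lists. Serotonin receptor genes stood at -0.57 (percentile 1.4) over 4 measured members, of which HTR3A was at least 2.47-fold lower, but at -0.22 (percentile 29.4) with a floor of 50.

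The largest higher genes above the floor on both arrays were the skeletal troponin gene TNNC2 (9.99-fold), the neuropeptide gene NPY (8.66-fold), MYBPH (7.53-fold), the kinesin gene KIF5C (7.4-fold) and the muscle caveolin gene CAV3 (6.29-fold). The other measured probe set of KIF5C had a log2 ratio of -0.14. The apolipoprotein genes APOA2 (13.8-fold), APOC3 (11.9-fold) and APOA1 (10.7-fold) were the largest lower ones with that limit, followed by SLC25A17 (9.59-fold) and HPGD (8.19-fold). For SLC25A17, the other measured probe set had a log2 ratio of -0.79. In all 497 genes were higher and 228 lower of 10401 measured. The higher share of 68.6% became 54.7% with equal medians and 86.3% with hybridisation controls, which placed the median of all measured genes at -0.13 and 0.17 in place of -0.02. Between these arrays the actin 3' to 5' ratio was 25.21 in N2 and 8.63 in N3, and the GAPDH ratio 7.1 and 2.1.

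**Figure D3:**
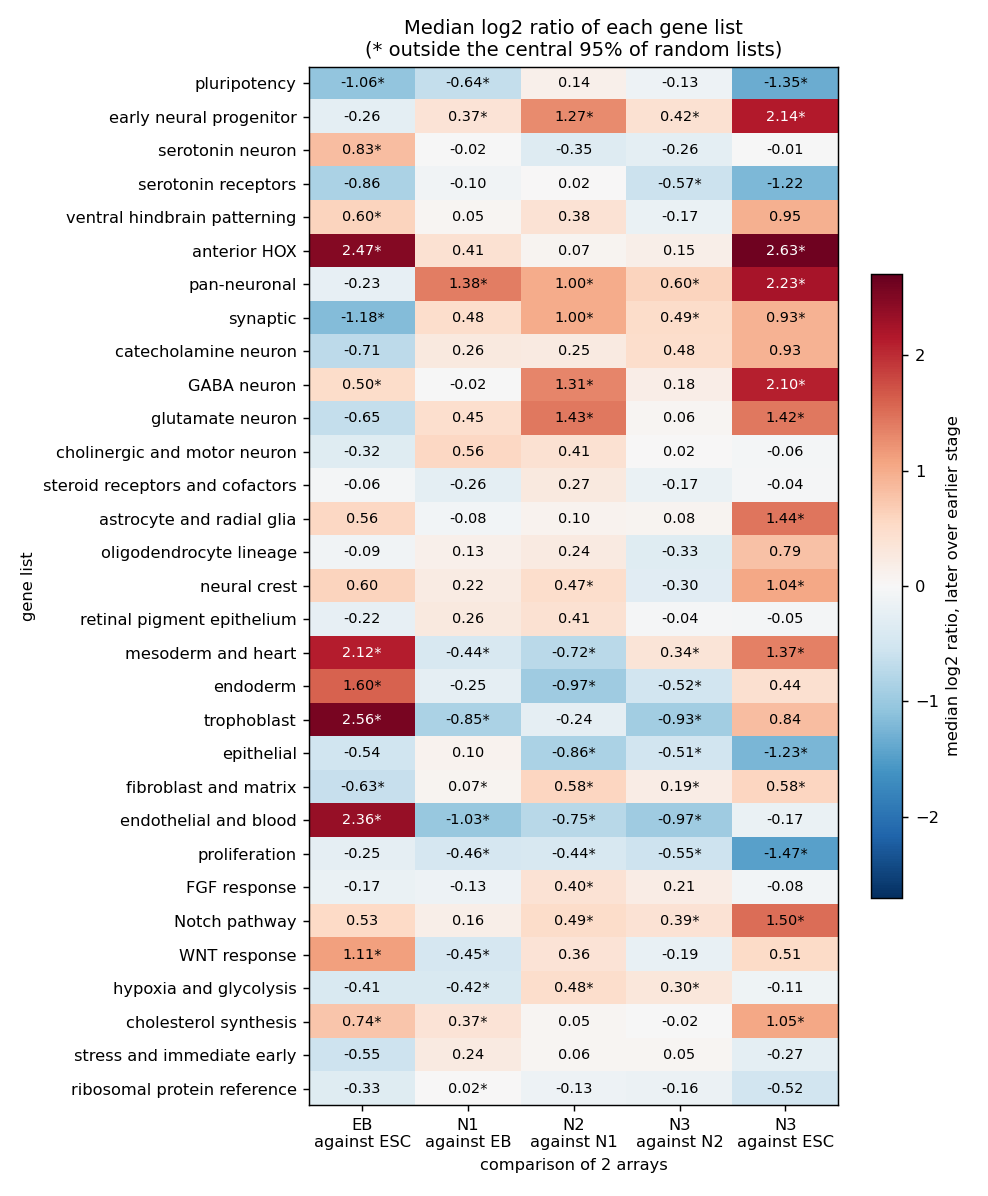
Median log2 ratio of the measured members of each of the 31 gene lists (rows) in the 5 comparisons (columns), red for higher and blue for lower in the later stage. The pan-neuronal median is 1.38, 1.00 and 0.60 in the 3 comparisons after EB, an asterisk marks lists that stand apart, and in N2 against N1 the FGF, Notch, hypoxia and neural crest medians turn negative under scaling to hybridisation controls, as all measured genes shift, but stay at percentiles 97.8 to 99.4.

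N3 against ESC gave the net difference over the whole protocol. Neuronal genes were higher for 11 of 17 members and lower for 1, with a median of 2.23 (percentile 100). DCX was 57.2-fold higher (186 in ESC and 10607 in N3), ELAVL4 at least 44.9-fold and STMN2 26.5-fold (935 and 24814). The other measured probe set of DCX had a log2 ratio of -0.02. Neural progenitor genes had a median of 2.14 (percentile 100), with HES5 at least 25.9-fold, DLL1 22.9-fold, SOX11 12.9-fold and PAX6 4.41-fold higher, while a second measured probe set of DLL1 had a log2 ratio of -0.84. SOX2, which acts in both stem and neural progenitor cells, was 19736 in ESC, 3413 in EB and 14978 in N3. PROM1 was 2.19-fold lower on its brightest probe set, and its other probe set moved the opposite way. The synaptic list stood at 0.93 (percentile 98.4), with SYT4 at least 81.7-fold higher.

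Among neuronal subtypes, GABA neuron genes had a median of 2.10 (percentile 99.9), with GAD1 at least 23.4-fold and GAD2 10.4-fold higher. Glutamate neuron genes had a median of 1.42 (percentile 98.0), with GRIA4 at least 6.48-fold higher, but lay at percentile 96.9 after quantile normalisation, 97.1 with equal medians and 97.0 with hybridisation controls. The cholinergic and motor neuron list did not stand apart (median -0.06, percentile 69.5, and 0.13 under scaling to hybridisation controls), nor did the catecholamine list (0.93, percentile 92.0), although the transcription factor gene ISL1 was at least 33.1-fold higher. Hindbrain and neck HOX genes were higher for 7 of 8 members (median 2.63, percentile 100), HOXA5 by 22.1-fold. Astrocyte and radial glia genes had a median of 1.44 (percentile 100), with SLC1A2 at least 23.4-fold and SLC1A3 10.9-fold higher. Neural crest genes stood at 1.04 (percentile 98.3), with TFAP2A at least 62.7-fold and SOX10 at least 5.48-fold higher, but at 0.11 (percentile 75.4) with the median of probe sets. Other measured probe sets had log2 ratios of -0.24 for SOX10 and of 3.09 and -0.37 for TFAP2A. The oligodendrocyte list (0.79, percentile 94.0), the ventral hindbrain list (0.95, percentile 95.9) and the retinal pigment epithelium list (-0.05, percentile 69.8, and 0.14 with hybridisation controls) did not stand apart. Notch pathway genes stood at 1.50 (percentile 100), although the other measured probe set of NOTCH3 moved opposite to the 3.69-fold higher signal of the brightest. That list did not stand apart with the median of probe sets (0.40, percentile 89.3) or a floor of 200 (0.80, percentile 97.2).

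The serotonin neuron list did not stand apart in N3 against ESC, with a median of -0.01 at percentile 64.6 over 9 measured members, of which 2 were higher and 3 lower, and with positive medians such as 0.36 under scaling to hybridisation controls. TPH1 and TPH2, which encode the rate-limiting enzymes of serotonin synthesis, lay below the floor on all 5 arrays, at most 23.3 for TPH1 and 16.2 for TPH2. HTR1A, a serotonin autoreceptor gene, reached at most 49.2. TPH1, TPH2, HTR1A and LMX1B were at the floor in both ESC and N3, so the list median leaves them out. A further 5 of the 18 listed genes, SLC6A4, DDC, QDPR, MAOB and NKX2-2, have no probe set here. The median therefore does not cover these genes. FEV, a transcription factor of serotonin neurons, was 113 in ESC, 89.6 in EB, 121 in N1, 66.0 in N2 and 85.3 in N3. SLC18A2, the vesicular monoamine transporter gene, was 86.9 in ESC, 189 in EB and 150 in N3. MAOA, which encodes an enzyme that breaks down serotonin, was 2.28-fold higher in N3 than in ESC (397 and 906), and GATA3 2.58-fold higher. The tetrahydrobiopterin synthesis genes SPR and GCH1, whose product is a cofactor of serotonin synthesis, were 4.46-fold and 3.37-fold lower. With the ESC array left out, the list median for N3 against EB was -0.92 (percentile 1.5). TPH1 and TPH2 lay below the highest of the 42 negative controls on each array (47.6 to 87.2). FEV lay above that control on every array, but only narrowly in N2 (66.0 against 64.8). It was below the floor in EB, N2 and N3, so its detection there is not shown. Absence of these transcripts was not shown.

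Among hormone receptors, ESR1 and PGR were below the floor on all 5 arrays, and ESR2 reached 105 in N1 and was below the floor elsewhere. The steroid receptor list did not stand apart (median -0.04, percentile 61.7, and 0.16 under scaling to hybridisation controls).

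**Figure D4:**
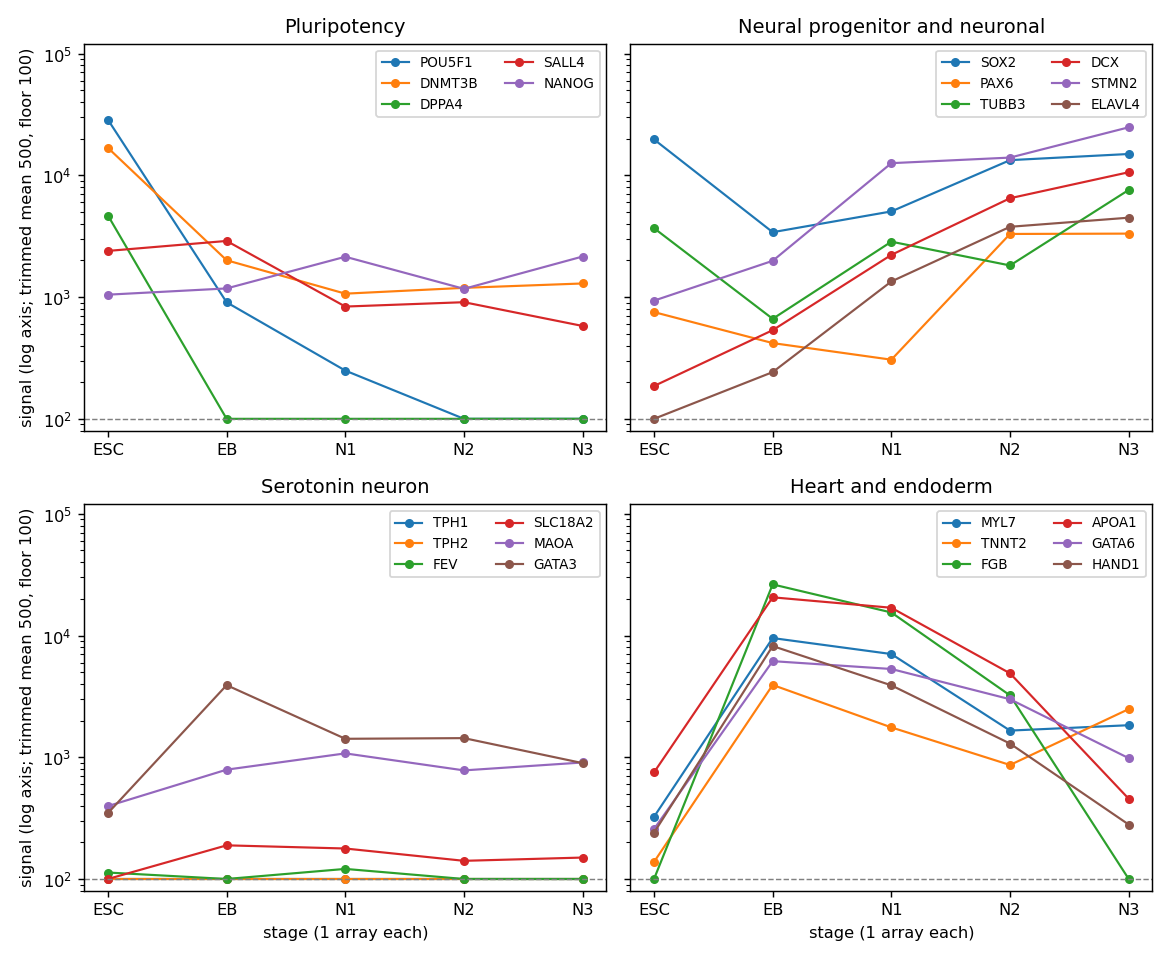
Signal of marker genes at each stage on a log axis, with 1 point per array and values below 100 drawn at the floor (dashed line). POU5F1 goes from 28621 in ESC to the floor in N2, DCX from 186 to 10607 in N3, TPH1 and TPH2 lie on the floor throughout, and FGB peaks at 26301 in EB.

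Genes of undifferentiated and dividing cells were lower in N3 than in ESC. The pluripotency median was -1.35 (percentile 0.0), with 8 of 11 members lower and 1 higher. POU5F1 was at least 286-fold lower, DPPA4 at least 46.8-fold and DNMT3B 13.0-fold, while NANOG was 2.06-fold higher (1047 and 2155). Without the ESC array, N3 against EB gave a pluripotency median of -0.41 (percentile 9.8). Proliferation genes were lower for 12 of 14 members (median -1.47, percentile 0.0), among them the DNA replication genes MCM3 (5.93-fold) and MCM4 (4.92-fold) and the mitotic kinase gene CDK1 (3.05-fold). Epithelial genes had a median of -1.23 (percentile 0.4), with CLDN6 86.9-fold and KRT8 13.5-fold lower. Of 9 measured members 5 were lower and 1 was higher, the keratin gene KRT18 (139 in ESC and 691 in N3). Mesoderm and heart genes had a median of 1.37 (percentile 100), with TNNT2 18.0-fold higher. Fibroblast and matrix genes had 5 of 12 members higher, LUM by at least 129-fold, and 4 lower (median 0.58, percentile 99.6, and 96.9 against unmatched random lists). Cholesterol synthesis genes stood at 1.05 (percentile 99.5, but 0.63 at 94.3 without probe sets able to bind related transcripts), with CYP51A1 5.42-fold higher. For CYP51A1, the other measured probe set had a log2 ratio of 0.95.

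Of genes above the floor on both arrays, the largest higher ones were H19 (103-fold), NCL (67.6-fold), CCDC80 (62.6-fold), DCX, the nuclear receptor gene NR2F1 (55.9-fold), the WNT receptor gene FZD10 (55.6-fold), DLK1 (51.1-fold), MOXD1 (43.2-fold), DNER (38.3-fold) and DACH1 (36.3-fold). The other measured probe set of NCL, the nucleolin gene, had a log2 ratio of -1.03. The largest lower ones with that limit were CLDN6, CYP26A1 (62.7-fold), the metallothionein gene MT2A (61.5-fold), SPP1 (46.5-fold), PMAIP1 (30.2-fold), the WNT receptor gene FZD5 (22.6-fold), IFITM1 (22.6-fold), the smooth muscle gene CNN1 (16.3-fold), NFE2L3 (16.2-fold) and the urokinase gene PLAU (15.9-fold). As for EB against ESC, the part of the ESC signal that came from feeder RNA was not measured. Stress genes (median -0.27, percentile 31.9), FGF response genes (-0.08, percentile 58.1) and ribosomal protein genes (-0.52, percentile 34.6) did not stand apart. Of 11232 measured genes 1935 were higher and 1847 lower. The higher share of 51.2% became 43.1% with no floor, 45.1% with the median of probe sets, 45.9% after quantile normalisation and 63.6% with hybridisation controls, which placed the median of all measured genes at 0.04 in place of -0.13. A second measured probe set moved the same way for 81.1% of genes past 2-fold and also passed 2-fold for 49.8%. Across all comparisons, 197 named differences had another measured probe set. In 120 of them at least 1 such probe set passed 2-fold the same way, and in 6 at least 1 passed 2-fold the opposite way.

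By stage, 582 genes were at least 2-fold above every other stage in ESC, 84 in EB, 36 in N1, 3 in N2 and 200 in N3. Among genes above the floor on at least 1 other array, the ESC genes furthest above their next stage were POU5F1 (31.6-fold), the interferon-induced gene TRIM22 (26.7-fold), VTCN1 (25.0-fold), the natriuretic peptide gene NPPB (22.5-fold) and SPP1 (21.5-fold). With the same limit for each stage, EB was led by TRPV2 (5.41-fold), the erythroid haem synthesis gene ALAS2 (4.57-fold), MTTP (4.4-fold), CCKBR (4.25-fold) and CREB3L3 (4.09-fold). N1 was led by HBE1 (9.28-fold), HBG2 (8.67-fold), HBA (8.55-fold), ITIH1 (6.03-fold) and APOA4 (3.99-fold). In N2 the ratios were small, at 2.37-fold for HSPA12B and 2.12-fold for NIPAL4, with EFEMP1 (1.92-fold), the growth factor gene IGF1 (1.91-fold) and COX18 (1.89-fold) within 2-fold. N3 was led by NPY (8.66-fold), MYBPH (7.53-fold), TNNC2 (7.28-fold), CAV3 (6.08-fold) and LCN2 (5.87-fold).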

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

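The test of scaling and the tests of probe sets by list were chosen only after the result was seen. For the 3 marker lists and the share of their members, a condition was added after the results were seen: a value counted against an explanation, and a share also for it, only where its 95% interval lay beyond the limit. Without that condition, red blood cells and probe sets reading other transcripts among the plasma protein genes would have counted as argued against, and such probe sets among the red blood cell genes as favoured.

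Of 27751 non-control probe sets without a single gene name, none of which enters a comparison by gene, 16780 were brighter than the highest negative control (87.2) on at least 1 array. They make up 60.5% of such probe sets, and 7570 were above that level on all 5 arrays.

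EB against ESC had more genes past 2-fold than any other adjacent comparison, 2622 against 1223 for N2 against N1. In the simulated data, noise of the size of the probe set spread took 1312 unchanged genes past 2-fold in EB against ESC. For N2 against N1 it took 486, and its share in the ranking was not tested. The control transcripts differed in their 3' to 5' ratios, which for GAPDH were 2.78 in EB and 1.94 in ESC and for EF1a 0.96 and 0.86. Loss of 5' signal may contribute to the ranking, since the actin 3' to 5' ratio was 15.19 in EB and 1.73 in ESC. The N2 and N1 arrays also differed in that ratio and share no array with EB against ESC, and there the genes lower in EB had a median -0.16 from that of genes within 2-fold (95% bootstrap interval -0.21 to -0.11) and the genes higher in EB 0.10 (0.06 to 0.15). The first lies between the shift of 0.25 set in advance for this explanation and the 0.10 set against it, and the second lies at 0.10 with an interval reaching past it, so loss of 5' signal cannot be told apart from the change of stage. Scaling may bear on the ranking, since EB against ESC had 2.09 to 2.73 times as many genes as the next adjacent comparison under 3 other scalings and the reported one but 0.95 times as many with hybridisation controls, where N2 against N1 reached 2730, EB against ESC had 2580, and the 2543 genes lower in N2 go with a shift of all measured genes to a median of -0.57.

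Genes of muscle, liver and blood were among the largest differences of a culture directed towards neurons, and were followed with marker lists written before the test, leaving out the genes already seen. Probe sets that read transcripts of other genes, as the cause of the whole pattern, fell on the unfavourable side of the limit of 3. Of 36 measured members 16 were at least 2-fold higher where 3.3 were expected, a ratio of 4.81 (95% Wilson interval 3.2 to 6.54). The muscle genes alone also exceed it (7 of 13, ratio 6.39, 3.46 to 9.12). The explanation stays open for the red blood cell genes alone (0 of 8, 0.0, 0.0 to 6.3). It stays open by a narrow margin for the plasma protein genes alone (9 of 15 where 1.8 were expected, 4.95, 2.95 to 6.61). These intervals treat genes as independent, which co-regulated genes on the same arrays are not, so they do not settle the question. The muscle list has 19 genes on the array that were not among those seen, and the plasma protein list 22. Only measured genes enter these shares and the medians below. The muscle genes left out were MYF5, MYF6, CKM, CHRND, CHRNG and TTN, below the floor in both N1 and N3. The plasma protein genes left out were F9, F10, C5, CPB2, ITIH2, FETUB and PROC, below the floor in both ESC and EB. Members such as MYH8 share a gene family with seen genes such as MYH3, so reading across such relatives is not excluded. Skeletal muscle cells in the N3 culture stay a candidate explanation, with a median log2 ratio of 1.68 for N3 against N1 over 13 genes, at percentile 100 (CASQ2 161 in N1 and 1982 in N3, KLHL41 103 and 2330), and so do liver or yolk sac cells in the EB culture, with 1.50 for EB against ESC over 15 genes, also at percentile 100 (SERPINA1 187 in ESC and 3923 in EB, APOM 371 and 4670). Of these genes, 1 muscle gene was at least 2-fold lower, ACTN3 (564 in N1 and 154 in N3). No plasma protein gene was, but APOE was 9677 in ESC and 8583 in EB. AFP, a plasma protein gene already seen, was 991 in ESC and 601 in EB. For red blood cells in the N1 culture the median over 8 genes was -0.02 (percentile 40.2), on the unfavourable side of the limit of percentile 50 set in advance, but its 95% bootstrap interval of -0.44 to 0.44 reaches past the 0.37 that the explanation needs, while ALAS2 was 789 in EB and 96.5 in N1 and TFRC 7268 and 3531. The erythroid list has 15 genes on the array that were not among those seen. Those left out of that median were below the floor in both EB and N1. They include HBB (46.1 in EB and 24.6 in N1), GATA1 (13.2 and 64.5) and AHSP (4.2 and 3.86). CASQ2, KLHL41, SERPINA1, APOM, TFRC, HBB, GATA1, AHSP, MYH8, ACTN3, APOE and AFP were chosen after their values were seen. So were the muscle and plasma protein genes named as left out. No sort or gate is given in the sources used here, and a change of programme within the cultured cells was not tested.

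TPH1, TPH2, LMX1B and HTR1A lay at the floor on all 5 arrays in a culture named for serotonin neurons, LMX1B being named after its values were seen. A candidate explanation is probe sets that do not respond. Of 3572 genes with several probe sets, of which at least 1 reached 1000, 724 (20.3%) had another at the floor on all arrays. That share lies between the limits set in advance, over 50% for this explanation and under 1% against it, so unresponsive probe sets cannot be told apart from low expression. A small share of serotonin neurons in the N3 culture stays open and was not tested.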

How the results depend on the processing

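The comparisons that leave out the ESC, EB or N2 array were chosen after the result was seen, and the other alternatives before the data were examined. For each value below that changed, the cause was not tested unless a cause is stated.

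Scaling to equal medians gave 2622 genes higher and 653 lower in EB against ESC, and 280 and 847 in N1 against EB. It gave medians of -0.29 for fibroblast and matrix genes (percentile 98.5) and -0.35 for ribosomal protein genes (97.7) in N1 against EB, where it moved all measured genes to a median of -0.37. Quantile normalisation gave 354 genes higher in N1 against EB and a ribosomal protein median of -0.04 (59.6). Scaling to the hybridisation controls gave 1492 genes higher and 75 lower in N1 against EB, 187 and 2543 in N2 against N1, and 828 and 131 in N3 against N2. By construction it shifts all genes of an array alike, to a median of 0.41 in N1 against EB and -0.57 in N2 against N1, and so turned signs while the lists still stood apart. In N1 against EB these were mesoderm and heart (0.03), proliferation (0.01), WNT response (0.04) and hypoxia and glycolysis genes (0.04), at percentiles 0.5, 0.4, 0.9 and 1.3. In N2 against N1 they were neural crest (-0.11), FGF response (-0.15), Notch pathway (-0.09) and hypoxia and glycolysis genes (-0.10), at percentiles 98.8, 97.8, 99.1 and 99.4.

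A floor of 50 gave 2038 genes lower in EB against ESC, 872 higher and 342 lower in N1 against EB, and 396 lower in N3 against N2. A floor of 200 gave 322 higher in N1 against EB, 149 lower in N3 against N2 and a ribosomal protein median of -0.10 in N1 against EB. With no floor, 2029 genes were higher and 3197 lower in EB against ESC, 1906 and 920 in N1 against EB, 1393 and 1740 in N2 against N1, and 1452 and 1182 in N3 against N2. In N3 against ESC it gave 3454 lower, and the synaptic median in EB against ESC was 0.06. Lower floors admit ratios between signals within the background by construction. The 4-fold threshold is stricter by construction and left 405 higher and 255 lower in EB against ESC, 56 and 10 in N1 against EB, 71 and 51 in N2 against N1, 36 and 22 in N3 against N2, and 726 and 316 in N3 against ESC.

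The median of a gene's probe sets gave 354 genes higher in N2 against N1 and 120 lower in N3 against N2. It turned the list medians of WNT response genes in EB against ESC (-0.21), neural crest (-0.01) and FGF response genes (-0.02) in N2 against N1, and ribosomal protein genes in N1 against EB (-0.03), none of which then stood apart (percentiles 36.2, 71.5, 69.2 and 79.7). It also turned the log2 ratios of SOX11 (-0.05) and TEK (-0.01) in EB against ESC, TFAP2A (-0.11) and MLANA (-0.02) in N2 against N1, and PROM1 (0.84) in N3 against ESC. Leaving out probe sets marked as able to bind related transcripts turned TPI1 in N2 against N1 (0.02).

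With the N2 array left out, N3 against N1 had 897 genes higher and 710 lower, set against 534 higher in N2 against N1 and 497 higher and 228 lower in N3 against N2. With the ESC array left out, N3 against EB had 1180 genes lower, a pluripotency median of -0.41 (percentile 9.8) and a serotonin neuron median of -0.92 (percentile 1.5). These settings compare other stages by construction.

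The other 66 alternative values of the 10 counts lay within 1.5 times the reported count. Of the alternative values of the 155 list medians, 1377 kept their direction and side of the limit or moved little, 62 no longer stood apart, 45 newly did, 39 moved and 17 reversed. Of those of the 466 named gene ratios, 3855 kept theirs, 280 no longer passed 2-fold, 18 newly did, 11 moved and 6 reversed. No paired analysis was possible because each stage has 1 array, and no replicate could be left out for the same reason. Signals near the floor of 100 limit what low transcripts can show, since 2490 genes were at the floor on all 5 arrays.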

Other observations

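The 3 marker lists used here were written after genes of these kinds had been seen among the largest differences. The list values below include comparisons not weighed above, and their percentiles describe these arrays and weigh no explanation. All genes named here that are not named elsewhere were chosen after their values were seen.

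The embryonic myosin gene MYH3 was 103 in N1, 2905 in N2 and 14054 in N3, and the myosin light chain gene MYL1 was 188, 2974 and 12049. MYOD1, a transcription factor of muscle precursors, was 13.1 in N1, 221 in N2 and 322 in N3. The acetylcholine receptor gene CHRNA1 was 7.25, 115 and 556. Of 14 measured muscle genes not seen beforehand, 9 were at least 2-fold higher in N3 than in N2 and 0 lower (median 1.44, percentile 100). Among those 9, TNNT1, TNNT3 and TNNC1 were low on the N2 array (977, 29.2 and 51.0). Against N1 they were 1.08-fold, 1.39-fold and 1.44-fold higher in N3. The N2 array had the highest actin 3' to 5' ratio, 25.21. N3 against N1, which skips it, had 7 of 13 members higher and 1 lower (median 1.68). For N2 against N1 the list did not stand apart, with 5 of 13 higher and 4 lower (median 0.21, percentile 93.7). CKM, the muscle creatine kinase gene, was 84.8 in N1 and 45.6 in N3, and ACTN3 was 564 and 154. None of the muscle, plasma protein or erythroid genes not seen beforehand is in any of the 31 lists, whereas ACTC1, MYL4, TNNT2 and MEF2C, already seen, are also in the mesoderm and heart list.

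Several plasma protein genes were highest in EB or N1 and lower in N3. FGB was 26301 in EB, 15461 in N1, 3222 in N2 and 71.2 in N3, and APOA1 was 20596, 16909, 4890 and 456. SERPINA1 was 3923 in EB and 13569 in N1, and AGT 1136 and 3286. Of 18 measured genes not seen beforehand, 4 were higher in N1 than in EB and 1 lower (median 0.41, percentile 99.9). In N2 against N1, 12 of 18 were lower and 0 higher (median -1.11, percentile 0.0), and N3 against N1 gave 13 of 17 lower (median -1.91, percentile 0.0). AFP, the fetal albumin-related gene, was 991 in ESC, 601 in EB and 437 in N3. The haemoglobin genes HBE1, HBG2 and HBA were 2077, 5079 and 1513 in N1, and 14.6, 43.0 and 15.9 in N3. The probe sets of HBG2 and HBA are marked as able to bind related transcripts.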
